A study of Mus musculus with 16 samples.

How the data were processed

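Meningeal ectopic lymphoid tissue (mELT), detached from the spinal cord, and lumbar lymph nodes (LN) of 3 male Thx2D2 mice (E21, E72 and F21) were compared. These mice carry a B cell heavy chain and a T cell receptor directed at myelin oligodendrocyte glycoprotein and fall ill without immunization. Per the labels, they were untreated, were killed 23 ± 3 days after disease onset and were perfused with PBS, and cells carrying CD45, a surface protein of leukocytes, were enriched with magnetic beads. Each tissue gave 3 libraries of gene expression, 3 of B cell receptors and, from mice E21 and E72, 2 of T cell receptors, all made with the 10x Genomics Immune Profiling kit. T cell receptors of mouse F21 were not analysed here.

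The expression matrices were deposited as raw counts of unique molecular identifiers (UMIs) per gene and cell barcode. They were made with Cell Ranger 5.0.0, per the file headers, on GRCm38, per the labels. The submitters' processing notes also name Cell Ranger 4.0.0, without its role, and the annotation release is not given in the sources used here. Each matrix had 32285 genes, and every barcode held at least 500 UMIs. The receptor tables were deposited with counts of UMIs and reads per assembled contig, and every contig in them was marked as belonging to a cell and as high confidence. Coordinates are 1-based, from the GENCODE vM21 annotation of GRCm38, in which 172 of the 172 named genes were found.

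Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run through scanpy 1.11.5 with an expected rate of 5%, found no usable threshold in 5 of the 6 libraries, where it marked between 0 and 6 barcodes. The barcodes with the highest scores were therefore removed instead, at 0.8% per 1000 barcodes, together with barcodes holding more than 5 UMIs of both the T cell and the B cell markers where the smaller set made up at least 10% of both. This removed 14.9, 12.5 and 8.85% of the mELT barcodes and 8.69, 21.6 and 6.96% of the LN barcodes of mice E21, E72 and F21. The 6 libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 and random seed 1. The 783 immunoglobulin, T cell receptor, mitochondrial and ribosomal genes were left out of the clustering. Mixed clusters were divided again at resolution 0.5 on 1000 genes and 15 components.

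Clusters were named from fixed marker genes, with at least 3 markers detected at 20 CPM (counts scaled to library size) and with the 10 genes of largest fold over cells of other lineages, after adding 20 CPM. Measured against all other cells instead, 9 clusters were led by markers of another class. These were B cell clusters 2 and 4.0 (oligodendrocyte markers) and 6 (1 monocyte marker), CD4 T cell clusters 7.3, 12.3, 12.7, 13.0 and 13.1 (dendritic, regulatory or CD8 T cell markers) and cluster 20, named microglia. Values without these 9 clusters are given beside the results they change. A cluster with at least 10% haemoglobin UMIs was called erythroid, and a regulatory T cell cluster needed 100 CPM of Foxp3. Clusters that met no rule stayed unnamed. The doublet rule, the thresholds of cluster naming, the comparison with other lineages, and the haemoglobin and Foxp3 rules were set after the data were seen.

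For B cells (B cell and germinal centre clusters, plasma cells left out) and for T cells (CD4, CD8 and regulatory clusters, γδ T and NK cells left out), raw counts were summed per library. They were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood test, tissue as the only term) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method. A gene changed where its adjusted p was under 0.05. Standard errors are the fold change divided by the root of the F statistic. The B cell sums held 14580598, 3057468 and 1607183 UMIs in mELT and 4303220, 4083378 and 491834 in LN of mice E21, E72 and F21. The T cell sums held 8862319, 2920695 and 650582 UMIs in mELT and 9846392, 12404971 and 5784004 in LN. On simulated B cell sums of 9916 genes, 38% of genes changed 2-fold and 87% of those changed 4-fold were recovered, and 8.76% of the calls fell on unchanged genes. For T cells, on 11090 genes, these values were 49, 83 and 7.04%.

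Gene lists fixed beforehand were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 23 lists of each cell class. Counts of list members are given over all genes tested and adjusted over the list alone. The genes named are, per cell class, up to 10 with the largest increase and 10 with the largest decrease among changed genes. These had a mean of at least 20 CPM, the same direction in all 3 mice and a level no more than 5-fold below the highest CPM in any other class of that tissue. Receptor, predicted, mitochondrial, ribosomal and haemoglobin genes were left out. Up to 4 members of each list with the smallest adjusted p were added. Marker genes of other cell types measure RNA from other cells. Results of some single genes are not reported here.

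Shares of cells were compared with exact two-sided permutation tests over libraries. With 3 libraries per tissue the smallest possible p is 0.1, with 2 per tissue it is 0.333, and over the 6 ways to match mELT with LN libraries it is 0.167. Shares of single libraries have 95% Clopper-Pearson intervals, and a share of 0 is limited by 3 counts. Intervals and limits cover counting error only. A clonotype is the same V gene, J gene and CDR3 nucleotide sequence of 1 heavy and 1 light chain (or 1 alpha and 1 beta chain), and an expanded clonotype has at least 2 cells. Expansion and sharing were averaged over 1000 draws of equal cell numbers, 118 cells per library for B cells and 437 for T cells. A class-switched cell has 1 heavy chain contig with an IgG, IgA or IgE constant gene. The heavy chain taken to be the knock-in is the commonest one, IGHV1-9 with IGHJ2 and a single CDR3.

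Both tissues came from the same 3 mice, so the libraries form pairs. Deviations from the tissue means over the 2000 most variable genes correlated within mice E21, E72 and F21 by 0.0723, 0.00529 and 0.123 in B cells and by 0.248, -0.179 and 0.122 in T cells. Fits with the mouse as a block were run for genes and gene lists and for the shares of cell classes, class-switched cells and expanded clonotypes, and their values are given where they change a call or move a count by more than 1.5-fold. The groups, tests, marker genes, gene lists and naming rule for genes were fixed before the data were examined. So were alternatives for cell filters, doublets, cluster resolution (0.5 and 2), normalization, low-count filter, DESeq2 1.42.0, equal cell numbers, receptor-based classes, the block and each library left out. Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.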

Results

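Single-cell gene expression was measured in CD45-enriched cells of mELT and LN from 3 Thx2D2 mice, with B cell receptors in all 6 libraries and T cell receptors in 2 libraries per tissue. The mELT expression libraries of mice E21, E72 and F21 held 7228, 2284 and 2917 barcodes with 43724630, 12329970 and 5899185 UMIs. The LN libraries held 4145, 8321 and 3550 barcodes with 19951141, 36558983 and 10998320 UMIs. After filtering, 5255, 1812 and 2442 mELT cells and 3320, 5097 and 3059 LN cells remained. Median UMIs per cell were 3768, 3615 and 1216.5 in mELT and 4129.5, 2899 and 1900.0 in LN, so mouse F21 was the shallowest in both tissues.

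The first comparison asks which immune cells populate the inflamed meninges and how they differ from those of the draining node. The meningeal libraries were rich in B cell-like clusters, which express the receptor subunit genes Cd79a and Cd79b, and in myeloid cells that were rare or unseen in the node. These were neutrophil-like cells with the calprotectin genes S100a8 and S100a9 and monocyte-like cells led by the granule enzyme genes Mpo, Prtn3 and Elane. Microglia-like cells carried the complement gene C1qa and the microglial genes Trem2 and Sparc. Plasma cell-like and erythroid cell-like clusters were also found mainly in mELT. CD4 T cell-like, CD8 T cell-like, γδ T cell-like and NK cell-like clusters took larger shares of the node.

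CD4 T cells made up 18.2 ± 5.28% of mELT cells and 47.6 ± 10.5% of LN cells (mean ± SD, n = 3 libraries each here and below). B cells made up 44.7 ± 12.5% and 24.9 ± 11.7%, with an mELT mean of 37.5% without mELT of E21 and an LN mean of 31.6% without LN of F21. Without the 3 B cell clusters led by markers of other cells when folds are taken against all cells, the B cell shares were 29.0 ± 15.8% and 20.4 ± 9.12%, and the 2 tissues overlapped. Neutrophils were 9.44 ± 5.50% of mELT (6.28% without mELT of F21) against 0.116 ± 0.0167% of LN. The monocyte-like progenitor cluster was 3.57 ± 1.998% against 0.330 ± 0.316%, with 22, 15 and 1 LN cells in E21, E72 and F21. Erythroid cells were 2.85 ± 1.69% against 0.0959 ± 0.139% (0.0163% without LN of E72, which held 13 of these cells), and haemoglobin transcripts took 0.296, 1.87 and 7.27% of all UMIs in mELT of E21, E72 and F21. γδ T cells were 0.307 ± 0.262% against 7.22 ± 6.75% (3.33% without LN of F21, which held 459 of these cells). The mELT value rests on 10, 11 and 3 cells in E21, E72 and F21. NK cells were 1.82 ± 1.01% against 4.71 ± 1.74% (3.71% without LN of E72) and CD8 T cells 0.642 ± 0.368% against 3.02 ± 1.08%.

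Microglia-like cells (cluster 20) made up 6.99 ± 4.49% of mELT cells, with 97, 163 and 247 cells, and no LN cell fell in this cluster. Among its 10 leading genes were 4 macrophage and 2 microglia markers, so the name is uncertain. Plasma cells made up 0.669 ± 0.631% of mELT cells, 53 cells in all, and none was found in LN. A count of 0 allows LN shares of up to 0.0904, 0.0589 and 0.0981% in E21, E72 and F21. Against the mean of these limits, the mELT shares were at least 84.7-fold higher for cluster 20 and at least 8.12-fold higher for plasma cells. Of the plasma cells 34 came from F21, and without mELT of F21 their share was 0.307% and the limit 3.73-fold. The limit for cluster 20 was then 65.8-fold, its lowest with 1 library left out. CD45 enrichment can shape the shares of microglia and erythroid cells.

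For these 10 classes the 3 mELT values lay apart from the 3 LN values, which gives the smallest possible exact two-sided permutation p of 0.1 and an adjusted p of 0.16 over the 16 classes, so none passed 0.05. An edgeR test of the cell counts gave adjusted p of 0.00981 for CD4 T cells, 9.06e-05 for γδ T cells, 3.36e-07 for neutrophils and 0.123 for B cells. The tissues overlapped for conventional dendritic cell 2-like (1.15 ± 1.02% against 0.430 ± 0.0944%), germinal centre B cell-like (0.268 ± 0.183% against 0.818 ± 1.27%) and macrophage-like cells (3.07 ± 1.56% against 2.77 ± 2.10%). They also overlapped for migratory dendritic cell-like (0.907 ± 0.759% against 2.30 ± 1.21%), plasmacytoid dendritic cell-like (0.628 ± 0.405% against 0.530 ± 0.353%) and regulatory T cell-like cells (1.25 ± 0.885% against 0.326 ± 0.0298%), with exact p between 0.2 and 0.9. Within each of the 3 mice, migratory dendritic cells were lower and conventional dendritic cells 2 and regulatory T cells higher in mELT than in LN (exact paired sign-flip permutation test, p = 0.25, the smallest possible). Single libraries moved these means, with 0.566% for conventional dendritic cells 2 and 0.478% for migratory dendritic cells without mELT of E72, an LN mean of 1.67% for the latter without LN of E72, and 0.826% for regulatory T cells without mELT of E21. Of the LN germinal centre cells, 76 came from mouse E21. Unnamed clusters held 3.59 ± 1.05% of mELT and 4.83 ± 2.88% of LN cells.

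**Figure D1:**
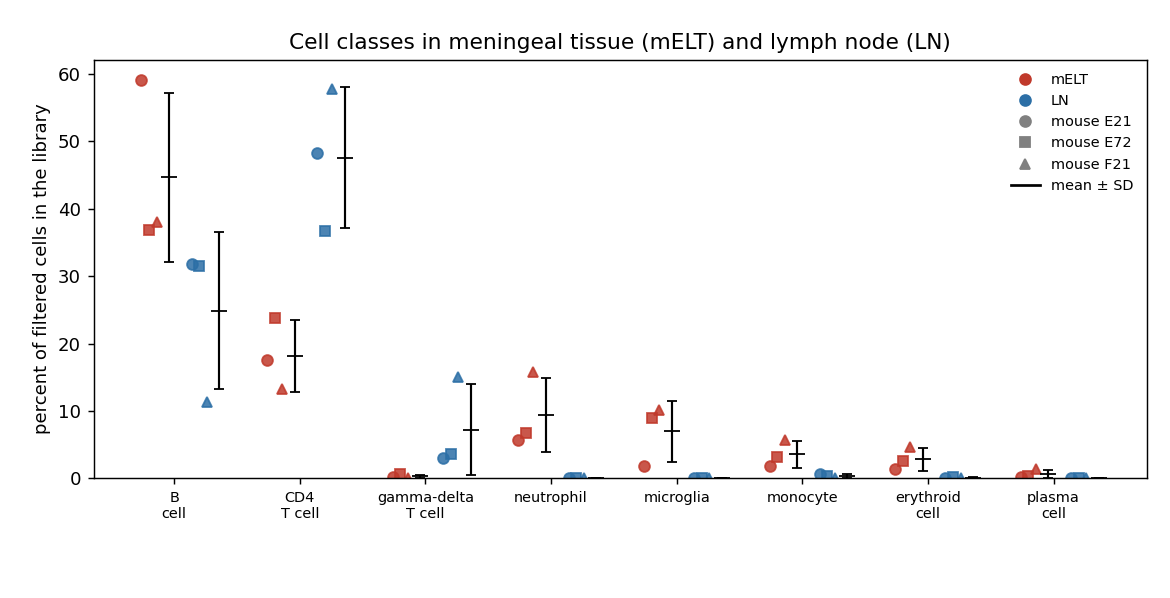
Percent of filtered cells per library in 8 cell classes, with red points for mELT, blue points for LN, a symbol per mouse, and black lines for the mean and SD of 3 libraries (cropped at 0). CD4 T cells averaged 18.2% in mELT and 47.6% in LN, and neutrophils 9.44% and 0.116%.

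The next comparison asks how T cells of the meningeal tissue differ from those of the node. Genes of T cell activation were among those that differed. Transcripts of inhibitory and costimulatory receptors were higher, such as Lag3, which binds MHC class II, Ctla4, which competes for costimulatory ligands, and Tnfrsf9 (4-1BB), a receptor of activated cells. So were transcription factor genes such as Bhlhe40, Nr4a1 and Egr1, of which Nr4a1 and Egr1 are early genes that also respond to handling of cells, and receptors that guide cells into inflamed tissue, such as Ccr2 and Cxcr6. Genes of resting cells that circulate through nodes were lower, among them S1pr1, needed to leave nodes, and Dapl1, typical of naive cells. Single interferon-induced genes, Gbp2 and Irf1, were lower, and Mki67, a gene of dividing cells, was higher. However, the interferon and cell cycle lists lost their calls with an estimated correlation (adjusted p between 0.263 and 0.373). The naive and central memory list narrowly lost its call there too, and the egress and homing list did not pass in the main test.

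Of 11090 genes tested with edgeR, 1571 changed, 1010 higher and 561 lower in mELT, and DESeq2 called 1415. Fewer changed without LN of E21 (836), LN of E72 (912) or mELT of E21 (1044). Of the changed genes, 386 stood more than 5-fold below their level in another cell class of the same tissue, 336 of them among the higher ones. RNA of other cells also moved with the tissue, since markers of neutrophils (median log2 fold change 7.31), macrophages (4.55), microglia (4.21) and erythroid cells (3.25) were higher in mELT T cells, and those of NK cells lower (-1.44), all past adjusted p 0.05 by camera. Markers higher as well were those of plasma cells (1.27), monocytes (1.44), innate lymphoid cells (2.54), cycling cells (2.004), CD4 T cells (0.97) and regulatory T cells (2.41). Those of B cells (0.35, adjusted p = 0.317), oligodendrocytes (0.79, 0.870) and the remaining classes (adjusted p from 0.135 upward) did not pass.

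The tissues were filled by different T cell clusters. Most mELT T cells lay in the subclusters of clusters 12 and 13, led by genes such as Tnfrsf4, Ctla4, Cxcr6, Izumo1r and Tcf7, and in mouse F21 also in cluster 21 (83 cells). Most LN T cells lay in clusters 14 and 21, which carry Dapl1, in cluster 25, and in cluster 22, led by the interferon-induced Ifit1 and Isg15. The fold changes therefore compare different mixtures of clusters. Within the activated clusters alone, chosen after the data were seen, 45 of 6658 genes changed, 39 of them shared with the 1571, and within the naive clusters alone 162 of 9422. The activated clusters held only 89, 117 and 65 LN cells of E21, E72 and F21, so lost calls there can come from few cells. All 17 lists that passed in T cells also passed in the same direction within the naive clusters. The clusters were divided by scores of the activation and naive lists, which are themselves among those tested. Cluster 12.3, counted as naive, had an activation score of 5.92, above the activated clusters 12.1 (5.64) and 10.2 (5.83). It held 49, 7 and 6 of the 109, 93 and 103 naive mELT cells of E21, E72 and F21. In LN it held 34, 58 and 29 of 1586, 1937 and 1836. The naive clusters alone thus still compared different mixtures and do not show a change within naive cells.

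Every gene named below changed in the same direction in all 3 mice. Among changed genes of at least 20 CPM whose level lay no more than 5-fold below that in another class, the largest increases were in Igfbp7 (chromosome 5, 77349240 to 77408041), a secreted growth factor-binding protein, at 4.71 ± 0.25 (log2 fold change ± SE, edgeR adjusted p = 1.71e-05), in Bhlhe40 at 4.11 ± 0.26 and in Tnfrsf9 (chromosome 4, 150914562 to 150946102) at 4.02 ± 0.21. Tnfrsf9 averaged 173 ± 37.3 CPM in mELT and 9.93 ± 2.53 in LN. They were followed by Nr4a1 (3.42), Podnl1 (3.26), Tnfsf11 (RANKL, 3.23), the transcription factor gene Myb (3.09), Endod1 (3.00), Cd200 (2.99), which encodes an inhibitory ligand, and the cytokine signalling inhibitor Cish (2.86). The largest decreases in this set were in the transporter gene Slc16a5 (chromosome 11, 115462474 to 115474398) at -4.51 ± 0.21 and in Ly6c1 (chromosome 15, 75044018 to 75048830), which encodes the surface protein Ly6C, at -4.22 ± 0.26. Ly6c1 averaged 36.2 ± 12.9 CPM in mELT and 664 ± 67.0 in LN, and 921 in γδ T cells of LN. Pdlim4 (-3.84), Tbxa2r (-2.29), the Notch pathway gene Dtx1 (-2.22), Igfbp4 (-2.19), the interferon-induced Tgtp1 (-2.17), Rasgrp2 (-2.12), which activates adhesion through Rap1, Dapl1 (-2.10) and Pdk1 (-1.94) followed. Tgtp1 lost its call without mELT of E21 (adjusted p = 0.0526). Within the activated clusters, Igfbp7, Bhlhe40, Tnfrsf9, Podnl1, Myb, Cd200, Lag3 and Izumo1r stayed higher and Slc16a5, Ly6c1, Pdlim4, Dtx1, Rasgrp2 and Dapl1 lower, past adjusted p 0.05.

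Among the lists of activation and of helper fates, 12 of 12 members of activation and exhaustion were tested and 11 rose, over all genes and adjusted over the list alone, with a median log2 fold change of 2.70 (camera adjusted p = 3.59e-30). Lag3 (chromosome 6, 124904361 to 124911705) rose by 4.58 ± 0.16, Ctla4 (chromosome 1, 60887000 to 60915832) by 2.77 ± 0.20 and Izumo1r, the folate receptor FR4, by 2.27 ± 0.17. Lag3 averaged 90.7 CPM in mELT T cells and 513 in microglia. In the regulatory T cell list 10 of 11 tested members rose, 11 adjusted over the list alone (median 2.14, adjusted p = 9.65e-25), with Il2ra at 2.18 and Foxp3, the regulatory lineage factor, at 2.14. All 9 tested Th17 members rose (2.01, 1.85e-16), such as Maf (2.54), Ccr6 (2.26; 157 CPM in B cells) and Rora (1.93), and 10 of 12 follicular helper members rose (2.13, 1.20e-15), among them Cxcr5 (2.40), which guides cells to B cell areas, and Icos (1.87). Within the activated clusters alone, the regulatory and Th17 lists did not pass (adjusted p = 0.878 and 0.859), and Foxp3 (-0.56), Ccr6 (-0.0471), Rora (-0.26) and Icos (-0.28) had the opposite sign. All 7 tested effector cytokine members rose (2.91, 2.48e-07), among them Il21, which helps B cells (3.51), and the growth factor gene Il2 (2.91), each under 10 CPM. In the Th1 list 5 of 12 rose and 1 fell, with the same counts adjusted over the list alone (0.67, 0.0123). That call was lost without LN of E21 (adjusted p = 0.0518), without mELT of F21 (0.295) and with an estimated correlation (0.373), and within the activated clusters the list was lower instead (-0.65).

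Migration and growth followed. Of 11 tested chemokine receptor and retention genes 7 rose, 9 adjusted over the list alone (1.53, 1.18e-10). Among them were Ccr2 (2.37, with 649 CPM in the monocyte-like progenitor cluster) and Cxcr6 (2.65). Within the activated clusters, however, the list had a median of -0.0145 and Cxcr6 was at -0.15. Of 12 naive and central memory genes 7 fell, 9 adjusted over the list alone (-0.87, 3.89e-08), such as S1pr1 (-1.10), with adjusted p = 0.0524 with an estimated correlation. The egress and homing list held 3 genes that rose and 5 that fell, 6 adjusted over the list alone, such as Ccr7 (-0.83; 0.0900 within the activated clusters). Its adjusted p was 0.0823, and it passed with the mouse as a block (0.0305), without a filter on low counts (0.0203), without mELT of E21 (0.0320) and without LN of F21 (0.0324). For G2/M, 16 of 18 genes rose, 18 adjusted over the list alone (2.13, 5.52e-12), such as Mki67 (2.61; 1027 CPM in erythroid cells) and Cks2 (2.16), with adjusted p = 0.263 with an estimated correlation. For S phase 4 of 16 rose, 10 adjusted over the list alone (0.66, 9.63e-05), with adjusted p = 0.373 with an estimated correlation. Within the activated clusters both cell cycle lists were lower instead (G2/M -0.85, S phase -0.93), as were Mki67 (-0.72) and Cks2 (-0.43) in value. NF-kB targets rose in 10 of 15 cases, 12 adjusted over the list alone (0.84, 6.12e-08), such as Nfkb1 (1.03). Glycolysis genes rose in 5 of 14, with the same count adjusted over the list alone (0.52, 2.13e-04), such as Tpi1 (1.79), with adjusted p = 0.326 with an estimated correlation. Immediate early and stress genes rose in 5 of 15 and fell in 1, or 6 and 1 adjusted over the list alone (0.33, 0.00489), with adjusted p = 0.373 with an estimated correlation, and lost the call without mELT of E72 (0.0501).

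Type I interferon genes fell in 6 of 16 cases, 11 adjusted over the list alone (median -1.34, adjusted p = 8.71e-06). Ifit2 (chromosome 19, 34550694 to 34576419) fell by 1.34. Interferon gamma genes fell in 10 of 16 and rose in 1, or 11 and 3 adjusted over the list alone (-1.01, 1.22e-05), with Gbp2 at -1.61, Irf1 at -1.24 and the feedback inhibitor Socs1 higher at 0.95. With an estimated correlation these lists had adjusted p = 0.373 and 0.263. Within mice E21, E72 and F21 the list means of log2(CPM + 1) differences were -0.704, -2.78 and 0.0621 for type I interferon and -0.560, -0.929 and -0.370 for interferon gamma. MHC class I genes fell in 2 of 12, with the same count adjusted over the list alone (-0.26, 0.0133), and lost the call without mELT of E72 (adjusted p = 0.0535) and with an estimated correlation (0.373). MHC class II genes rose in 3 of 12, 8 adjusted over the list alone (1.11, 5.32e-04), such as H2-DMa (1.21), with adjusted p = 0.388 with an estimated correlation. H2-DMa was at 112 CPM in mELT T cells and 609.5 in B cells. Cytotoxicity (2 rose, 2 fell, or 2 and 3 adjusted over the list alone; adjusted p = 0.521), TCR signalling (4 and 3, or 5 and 3; 0.25004), hypoxia (2 and 1, or 4 and 2; 0.663), cholesterol and lipid handling (2 rose by both counts; 0.754) and oxidative phosphorylation (no gene; 0.521) did not pass. For cholesterol, the median was -0.04 and the mean 0.42. Calls of activation, regulatory, Th17, follicular helper, chemokine receptor, NF-kB and effector cytokine lists held with an estimated correlation, with adjusted p from 0.0105 to 0.0412.

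**Figure D2:**
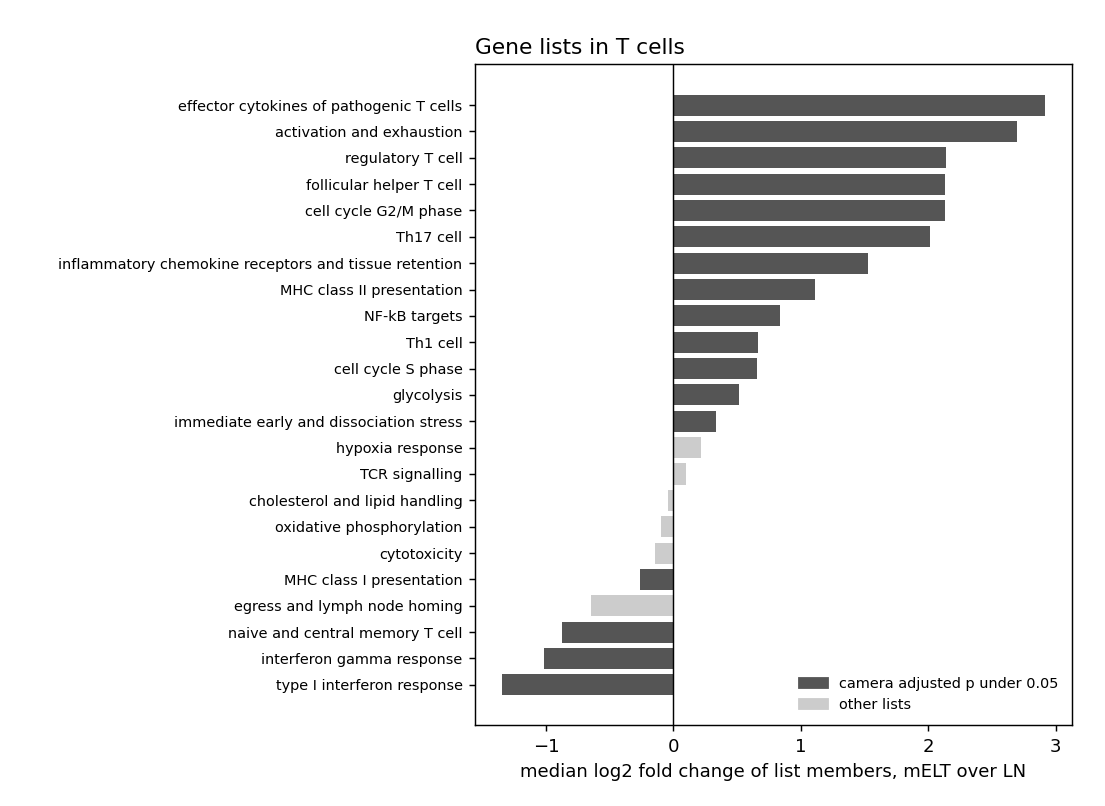
Median log2 fold change (mELT over LN) of the tested members of 23 gene lists in T cells, with dark bars for lists past adjusted p 0.05 by camera and light bars for the others. Effector cytokines reached 2.91 and the type I interferon response -1.34.

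B cells were compared to ask whether those lodged in the meninges carry another state than node B cells. Of the genes that changed, many belong to neutrophils and erythroid cells, and several others to myelin-forming cells. Mbp and Mobp, which encode myelin basic protein and a related protein of the myelin sheath, Plekhb1 and Bcas1, which are expressed in oligodendrocytes, and S100b, a calcium-binding protein gene of glia, were all higher in mELT B cells. Egr1, an early gene switched on by receptor signals and by handling of cells, was also higher. The mean over the genes induced by type I interferon was lower in mice E21 and E72 but not in F21. None of these genes passed the test across all genes, and the list had adjusted p = 0.363 with an estimated correlation.

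Of 9916 genes tested with edgeR in B cells, 20 changed, 16 higher and 4 lower, with 769 at an unadjusted p under 0.05. DESeq2 called 83, and edgeR with the mouse as a block called 56, in both cases with all 20 among them. The count depended on single libraries. It was 5 without LN of E21, 8 without LN of E72, 12 without mELT of E72, 13 without LN of F21 and 112 without mELT of E21, and 2 without both libraries of mouse F21. Of the 20 genes, 12 stood more than 5-fold below their level in another class, such as the neutrophil genes S100a8 and S100a9, the haemoglobin gene Hbb-bs and, among the lower ones, the macrophage genes Marco and Cd209b. Markers of neutrophils (median 8.4996), erythroid cells (7.29), oligodendrocytes (5.72), microglia (2.37) and macrophages (2.30) were higher and those of T cells lower (-0.74) in mELT B cells, with adjusted p of 6.69e-05 or less by camera. Markers of regulatory T cells were higher too (1.15, 0.0230), and those of B cells (-0.03, 0.521), plasma cells (0.555), monocytes (0.775), cycling cells (0.198) and the other classes did not pass. Most mELT B cells lay in clusters 0, 2, 3, 4.0, 4.1, 4.2 and 18, where cluster 2 was led by Mbp, Il4i1 and Cd83 and cluster 4.0 by Cldn11 and Mag. Most LN B cells lay in clusters 0, 2, 3, 4.2 and 18, and cluster 6, led by Ifit3, held 75 and 161 LN cells of E21 and E72 and 0 of F21.

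Mbp (chromosome 18, 82475146 to 82585637) rose by 5.43 ± 0.48 (log2 fold change ± SE, edgeR adjusted p = 0.00361), from 28.5 ± 5.05 CPM in LN to 1141 ± 624 in mELT. Mobp (chromosome 9, 120149707 to 120181484) had 1464 UMIs in mELT and 0 in LN B cells. Its mELT mean of 135 ± 88.5 CPM was at least 53.6-fold higher than the mean of the LN limits per library (edgeR adjusted p = 0.0226). With 1 library left out, this bound ranged from 37.9-fold (without mELT of E72) to 188-fold (without the shallow LN library of F21). S100b (chromosome 10, 76253853 to 76261159) had 697 UMIs against 1, a pooled ratio of 322 (95% counting interval 57.5 to 12718; adjusted p = 0.00920). Plekhb1 (chromosome 7, 100642892 to 100662414) had 725 against 1, a ratio of 334 (59.8 to 13229; adjusted p = 0.00649). Bcas1 (chromosome 2, 170346991 to 170427845) rose by 6.70 ± 0.84 (adjusted p = 0.00953) and Egr1 (chromosome 18, 34859823 to 34864984) by 1.67 ± 0.27 (adjusted p = 0.0470), from 67.4 ± 14.0 to 199 ± 61.5 CPM. The direction was the same in all 3 mice for each of these 6 genes. The lower genes were the macrophage genes Marco and Cd209b, Ly6c1 and the V gene Ighv1-26.

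Mbp kept its call in B cells with each library left out in turn (adjusted p up to 0.0428, without LN of F21), but not without both libraries of F21 (0.0763), where Mobp (0.213), S100b (0.140), Plekhb1 (0.0792), Bcas1 (0.121) and Egr1 (0.0892) lost theirs too, or with classes taken from receptors (0.0988). Egr1 lost its call with classes taken from receptors (0.508), at Leiden resolution 0.5 (0.0596), at 500 genes or more per cell (0.0627), at up to 5% mitochondrial UMIs (0.0652) and without barcodes that hold both receptors (0.0523). With classes taken from receptors, Mobp, S100b, Plekhb1 and Bcas1 were not among the genes tested. There, 9 of 7433 genes changed, 3 of them among the 20 of the main fit. Without LN of E21, adjusted p was 0.0784 for Plekhb1, 0.0815 for Mobp, 0.104 for S100b, 0.0892 for Bcas1 and 0.188 for Egr1. Without LN of E72 it was 0.0759 for Mobp and S100b, 0.0884 for Bcas1 and 0.0974 for Egr1, and without LN of F21 0.0780, 0.0589, 0.0549 and 0.183. Without mELT of E72, Mobp (0.0521) and Egr1 (0.118) lost their calls, and without mELT of F21 Mobp did (0.0658). Without the clusters led by markers of other cells, 18 of 9183 genes changed, 17 of them shared. Mbp was then higher by 4.29 ± 0.43 (adjusted p = 0.00314), whereas Bcas1 (0.0665) and Egr1 (0.415) did not pass. Mbp reached at least 1 UMI in 35.5, 73.3 and 53.6% of mELT B cells of E21, E72 and F21, and in 8.84, 8.20 and 3.70% of LN B cells. In T cells Mbp rose by 0.79 (edgeR adjusted p = 0.0467), from 76.1 to 139 CPM. Mobp had 0 UMIs in T cells of LN as well.

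**Figure D3:**
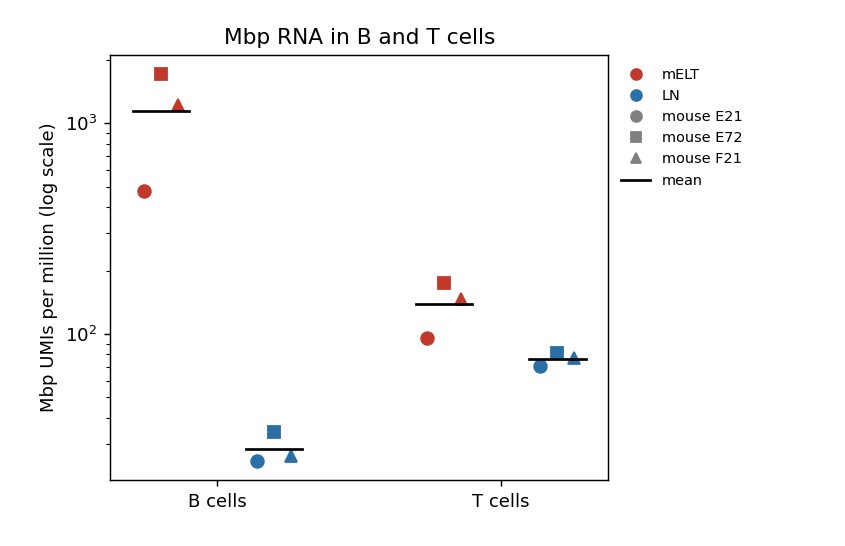
Mbp CPM (log scale) in summed B and T cells of each library, with red points for mELT, blue points for LN, a symbol per mouse and black lines for the mean of 3 libraries. B cells averaged 1141 in mELT and 28.5 in LN.

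Of the 23 lists in B cells, 5 passed camera with the preset correlation and 13 had an unadjusted p under 0.05. The type I interferon list was lower, with 0 of 16 tested genes changed over all genes and 16 lower adjusted over the list alone (median -1.71, adjusted p = 2.56e-16), such as Irf7 (-2.24), which amplifies the response, and Ifit2 (-2.22, adjusted p = 0.170). The list had adjusted p = 0.363 with an estimated correlation. Within mice E21, E72 and F21 its mean log2(CPM + 1) difference was -1.02, -2.89 and 0.176, so this mean showed no decrease in mouse F21. LN of F21 was shallow, with 3 UMIs there equal to 6.10 CPM, and single members can differ from the mean. Interferon gamma genes were lower with no member changed over all genes or adjusted over the list alone (-0.51, 1.13e-04), such as Ifi47 (-1.14), which encodes a GTPase, with adjusted p = 0.394 with an estimated correlation. Immediate early and stress genes were higher (0.85, 1.26e-05), with 1 of 15 changed and 3 adjusted over the list alone, such as Egr1 and Hspa1a (3.76, adjusted p = 0.397), a heat shock gene, and with adjusted p = 0.363 for the list with an estimated correlation. The age-associated and B-1 list was higher (0.47, 4.68e-04), with 0 of 8 over all genes and 4 adjusted over the list alone, such as Bhlhe41 (2.35), a regulator of B-1 cells, and Fcrl5 (1.28), an inhibitory receptor gene, and had adjusted p = 0.363 with an estimated correlation. Its member Apoe (2.30) was at 32179 CPM in microglia. MHC class I genes were lower with no member changed (-0.24, 0.0467). That call was lost with the mouse as a block (0.0739) and without LN of E21 (0.143), LN of E72 (0.163), mELT of E72 (0.0817), mELT of F21 (0.174), both libraries of F21 (0.0570) or precursor clusters (0.0833, chosen after the data were seen), and the list had adjusted p = 0.603 with an estimated correlation.

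None of these 5 B cell list calls held with an estimated correlation. There, 1 of 23 lists had an unadjusted p under 0.05, and with fry, also in limma, 0 lists passed and 2 had an unadjusted p under 0.05. The number of lists past the threshold was 8 without mELT of E21, LN of E21 or LN of F21 and 9 without mELT of E72. Not passing were MHC class II (adjusted p = 0.535), NF-kB targets (0.0646), S phase (0.535), G2/M (0.0769), oxidative phosphorylation (0.983), glycolysis (0.165), hypoxia (0.0514), egress and homing (0.0785) and chemokine receptors (0.0785). Cholesterol (0.920), naive follicular (0.0785), germinal centre (0.983), plasma cell (0.991), memory (0.562), cytokine (0.865), BCR signalling (0.0865) and BAFF and APRIL receptor genes (0.521) did not pass either. No member of these lists changed over all genes. Adjusted over the list alone, 1 member each of hypoxia, chemokine receptors, memory and BAFF and APRIL receptor genes was higher, and 2 cholesterol genes were higher and 1 lower. The switched immunoglobulin list had adjusted p = 0.0785 (0.00138 with the mouse as a block), with 1 member higher adjusted over the list alone. For B cell cytokines, BAFF and APRIL receptors, oxidative phosphorylation, plasma cell and cholesterol genes, the median, mean and test differed in sign.

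B cell receptors were read to ask whether meningeal B cells use the engineered heavy chain, switch class and expand as node B cells do. Among cells with a heavy chain, the mean share of the engineered chain was lower in mELT and that of IgA higher, a class reached by switching after activation, but with 3 mice no exact test of shares can pass 0.05. Few meningeal B cells gave a heavy chain contig at all, however. A contig was found for 5.56 (95% Clopper-Pearson interval 4.78 to 6.42), 27.1 (23.8 to 30.6) and 4.05% (2.88 to 5.52) of mELT B cells of E21, E72 and F21, and for 57.4 (54.4 to 60.3), 49.1 (46.7 to 51.6) and 63.5% (58.3 to 68.6) of LN B cells. The means were 12.2 ± 12.9% and 56.7 ± 7.23% (n = 3, exact two-sided permutation p = 0.1, the smallest possible). For light chains they were 44.2 ± 24.1% and 75.2 ± 10.6% (exact p = 0.2). Heavy chain values in mELT therefore describe a minority of B cells.

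The knock-in chain IGHV1-9/IGHJ2 was carried by 40.9 ± 25.9% of mELT and 81.8 ± 11.3% of LN cells with a heavy chain (n = 3, exact p = 0.1). Without mELT of E21 the mELT mean was 55.4%. The mELT shares were 11.8% (Clopper-Pearson 8.18 to 16.4) in E21, 61.5% (55.8 to 67.1) in E72 and 49.3% (40.8 to 57.8) in F21. Class-switched heavy chains were found in 21.01 ± 12.9% of mELT and 1.74 ± 2.33% of LN cells (n = 3, exact p = 0.1). These were 17.1, 10.5 and 35.5% of 234, 286 and 141 mELT cells and 4.42, 0.545 and 0.251% of 837, 1285 and 399 LN cells. Without mELT of F21 the difference fell from 19.3 to 12.1 percentage points, and without plasma cell clusters, a comparison chosen after the data were seen, the shares were 10.7 ± 5.89% and 1.33 ± 1.65%. IGHA made up 11.8 ± 8.24% of mELT cells and 0 of LN cells, which allows up to 0.358, 0.233 and 0.752% in LN of E21, E72 and F21 (exact p = 0.1, adjusted 0.35). Without mELT of F21 the mELT mean of IGHA was 7.05%. Of the mELT barcodes with IGHA, 13 lay in B cell clusters, 1 in germinal centre clusters, 18 in plasma cell clusters and 4 in CD4 T cell clusters, while 13 were doublets and 18 were not among the filtered cells. IGHG1 made up 6.85 ± 4.99% and 1.10 ± 1.84% (exact p = 0.2, adjusted 0.35), with overlap between mELT of E72 (2.10%) and LN of E21 (3.23%). Its mELT mean was 4.25% without mELT of F21, and its LN mean 0.0389% without LN of E21. IGHM was 62.1% in mELT and 71.9% in LN and IGHD 16.9% (9.82% without mELT of E72 and 23.3% without mELT of F21) and 26.3%. IGHG2B, IGHG2C and IGHG3 rested on few cells.

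Expanded clonotypes held 28.5 ± 18.0% of mELT and 49.9 ± 7.03% of LN cells at 118 cells per library (n = 3, exact p = 0.2), and without mELT of E21 the difference shrank from -21.4 to -12.5 percentage points. By heavy chain alone these shares were 46.4 ± 23.5% and 82.2 ± 11.4%, close to the knock-in shares, because every cell with the knock-in chain shares its sequence. By light chain alone they were 74.2 ± 3.31% and 78.0 ± 2.01%, a difference of only -3.84 percentage points. With both chains but outside plasma cell clusters, at 85 cells per library, they were 18.6 ± 9.77% and 44.0 ± 7.26% (exact p = 0.1), and the tissues lay apart. Clonotypes of mELT were found in LN of the same mouse for 20.4 ± 13.9% of cells (n = 3 pairs) and in LN of another mouse for 17.4 ± 11.0% (n = 6 pairs, exact p = 0.167, the smallest possible). Most sharing was therefore also seen between animals, where it cannot come from migration. Of the 3 most used heavy chain V genes, IGHV1-9 made up 44.8 ± 22.8% in mELT and 82.9 ± 10.6% in LN (exact p = 0.1). IGHV1-53 made up 2.70 and 0.545%, with 5.34, 1.34 and 1.41% in mELT of E21, E72 and F21, and IGHV1-26 1.69 and 1.42%. Of kappa genes, IGKV17-127 made up 13.1 and 10.7% (exact p = 0.3, adjusted 0.48), IGKV1-117 6.30 and 7.75% (0.7, adjusted 0.7) and IGKV6-32 6.25 ± 0.690 and 3.38 ± 0.583% (0.1, adjusted 0.4). Of lambda genes, IGLV1 made up 76.0 and 88.9%, IGLV2 18.8 and 9.12% (both 0.1, adjusted 0.15) and IGLV3 5.22 and 2.01% (0.3).

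**Figure D4:**
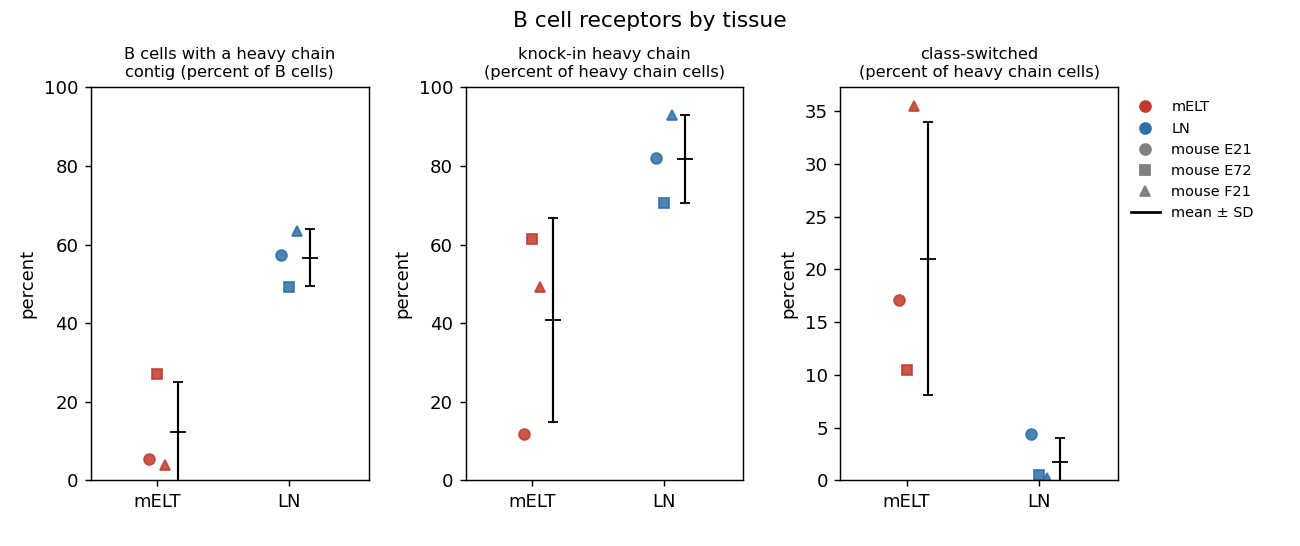
B cell receptor shares in percent per library: B cells with a heavy chain contig (left), heavy chain cells with the knock-in chain (middle) and class-switched heavy chain cells (right), with points coloured by tissue, a symbol per mouse and lines for mean and SD of 3 libraries (cropped at 0). The means were 12.2 and 56.7%, 40.9 and 81.8%, and 21.01 and 1.74% in mELT and LN.

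T cell receptors show whether T cells of both tissues express the engineered 2D2 receptor, the check of the animals' genotype. Nearly all did. TRAV9D-3 with TRAJ23 was carried by 97.8 ± 2.43% of mELT and 98.8 ± 0.330% of LN cells with 1 alpha chain (n = 2 libraries each, exact two-sided permutation p = 1, smallest possible 0.333), and TRBV16 with TRBJ1-1 by 98.002 ± 1.23% and 99.2 ± 0.447% of cells with 1 beta chain (exact p = 0.333). The next most used genes, TRAV12-2 and TRAV8D-2 or TRBV3 and TRBV1, each stayed under 1%. Expanded clonotypes accordingly held 98.2 ± 1.86% and 99.0 ± 0.425% of cells (exact p = 1). Clonotypes of mELT were found in LN of the same mouse for 97.8 ± 2.51% of cells and of the other mouse for 97.7 ± 2.57% (n = 2 pairs each, exact p = 0.5, the smallest possible of 2 matchings). With a single receptor in nearly all cells, expansion and exchange of T cells between tissues cannot be read from these sequences.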

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

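The comparisons without both libraries of mouse F21, within activated or naive T cell clusters, without plasma cell or precursor clusters and without clusters led by markers of another class were added after the data were seen, as were fold limits and receptor chain shares with each library left out. Of 288 values for the named cell classes (their shares, and how many lie apart) under other settings, 273 kept their direction and their side of the threshold, as did 1925 of 2105 for named T cell genes, 207 of 237 for T cell lists, 104 of 134 for named B cell genes and 48 of 65 for B cell lists. All values for V gene use (29), class-switched cells (11), expanded B cells (14) and shared clonotypes kept their direction. The exact tests of shares and clonotypes cannot reach 0.05 at these sample sizes, so there only a change of direction could have shown. Where values differed, the cause was not tested, except that within activated or naive clusters fewer cells and genes were tested. LN of F21 held the fewest B cell UMIs (491834). With equal cell numbers per library 21 of 7802 genes changed in B cells, 14 of them among the 20 of the main fit.

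In B cells, 20 genes changed. The count was 33 with doublets kept, 83 with DESeq2 and 372 without a filter on low counts. It was 9 with classes taken from receptors (3 of them among the 20) and 2 without both libraries of F21. With 1 library left out it ranged from 5 (without LN of E21) to 112 (without mELT of E21). With the mouse as a block (paired) it was 56. The block also ended the calls of the MHC class I list in B cells (adjusted p = 0.0739) and of Mcm6 in T cells (0.0664), brought in the switched immunoglobulin list in B cells (0.00138) and the egress list in T cells (0.0305), and changed no other call of a named gene, list or share. Over all T cell genes it gave 1394, of which 1267 were among the 1571. Of the B cell lists, 5 passed. The count was 12 without a filter on low counts, 0 with an estimated correlation in camera, 0 with fry, and from 4 (without mELT of F21) to 9 (without mELT of E72) with 1 library left out.

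In T cells, 1571 genes changed. The count was 840 with equal cell numbers, 45 in activated and 162 in naive clusters alone, and from 836 (without LN of E21) to 1624 (without mELT of F21) with 1 library left out. Of the T cell lists, 17 passed, as in naive clusters alone (17, all in the same direction), against 10 in activated clusters alone, 7 with an estimated correlation and 11 with fry. The 10 in activated clusters were 4 higher and 6 lower lists. Of the 16 lists of the main test that were tested there, 7 kept their direction and call. The naive clusters alone still held different mixtures of clusters in mELT and LN. In activated clusters alone, list medians turned for S phase (-0.93), G2/M (-0.85), chemokine receptors (-0.0145) and Th1 genes (-0.65), and the regulatory list had a median of 0.0912 with a test in the lower direction. Log2 fold changes there also turned for Uhrf1 (-1.57), Dtl (-0.50), Gins2 (-0.85), Mcm6 (-0.60), Cks2 (-0.43), Hmgb2 (-0.58), Cenpe (-0.47), Mki67 (-0.72), Ccr7 (0.0900), Ccr6 (-0.0471), Cxcr6 (-0.15), Rora (-0.26), Il18r1 (-0.27), Hopx (-0.65), Icos (-0.28), Foxp3 (-0.56), Lta (-0.0649) and Cst7 (-0.0790).

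An edgeR test of cell counts brought 7 classes past the threshold. Log2 fold changes were -1.39 for CD4 T cells, -4.60 for γδ T cells, 4.72 for erythroid cells and 10.93 for cluster 20. They were 3.42 for the monocyte-like progenitor cluster, 6.31 for neutrophils and 7.54 for plasma cells. Differences in percentage points that changed sign were those of macrophages without both libraries of F21 (-0.761) and at up to 5% mitochondrial UMIs (-0.135), and of plasmacytoid dendritic cells at Leiden resolution 0.5 (-0.00121). The difference of the unnamed clusters, -1.24, changed sign at up to 5% mitochondrial UMIs (1.08), at Leiden resolution 2 (0.543), without LN of E72 (0.278) and, since clusters then become unnamed, without clusters led by markers of another class (17.997). With 1 library left out they ranged from -0.823 (LN of F21) to 1.26 (LN of E72) for macrophages, from -0.926 (LN of F21) to 0.186 (LN of E21) for germinal centre B cells, from -2.59 (LN of E21) to 0.278 (LN of E72) for unnamed clusters and from -0.121 (mELT of F21) to 0.279 (mELT of E21) for plasmacytoid dendritic cells.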

Other observations

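Among the tests below, those of the share of myelin transcripts in few droplets and of the knock-in receptor were written before their results were seen, and all others were chosen after.

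B cells of mELT held RNA of oligodendrocytes, the cells that make myelin, with Mobp at 1464 UMIs in mELT and 0 in LN B cells. Free RNA in the droplets would reach T cells as well, but Mbp and Mobp together were at least 5.36 times higher in B than in T cells of each mELT library (95% counting interval of the lowest ratio 4.99 to 5.76). That ratio took in B cell clusters 2 and 4.0, led by oligodendrocyte markers. Cluster 2 held 585, 311 and 66 and cluster 4.0 63, 91 and 216 of the 3113, 675 and 938 mELT B cells of E21, E72 and F21. No cluster could be named oligodendrocyte, and no ratio without these clusters was taken. Part of the excess may therefore come from the classing, and free RNA is not excluded. Whole oligodendrocytes in the droplets of a few B cells lack CD45, so its enrichment argues for few of them, but its purity was not measured and they stay open, since the top 5% of mELT B cells by Mbp held 56.2, 28.2 and 40.4% of its UMIs in E21, E72 and F21, while 35.5, 73.3 and 53.6% of cells held at least 1. Uptake through the knock-in receptor stays open too, since cells with the knock-in chain held 17.7, 5.11 and 0.184 times the myelin UMIs of cells with other heavy chains, where a single cell held 83 of the 117 UMIs of knock-in cells in E21 and 84 of the 96 of other cells in F21. Without the highest cells these ratios were 6.43, 7.63 and 1.22 (0.589 to 2.69), and a difference of the tissue itself was not tested.

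Few mELT B cells gave a heavy chain contig (12.2% against 56.7% in LN). A mean Ighm level 1.34 times that of LN argues against lower Ighm mRNA in the summed B cells. These sums also held RNA of other cells, so Ighm free in the droplets is not excluded. Lower depth of the expression libraries is argued against by mELT of E21. It had more UMIs per cell than LN of F21 but 0.0875 times its recovery, the lowest ratio of the pairs compared. Contigs of the separate receptor libraries held 1920764, 1742682 and 3788040 reads in mELT and 2896518, 1617076 and 5018336 in LN of E21, E72 and F21. Depth of the receptor libraries was not tested and stays open. That a few barcodes took most heavy chain UMIs stays open too. The 10 barcodes with most held 68.9, 61.5 and 49.6% (49.0 to 50.2) in mELT and 8.21, 2.87 and 9.51% in LN. Its limit was changed after these values were seen, from any value below 50% to an interval below 50%, and under the first limit it would have been argued against. A difference of the tissue itself was not tested.

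Cells of bone marrow type were found in mELT. Progenitors with Mpo and Elane made up 3.57% of mELT and 0.330% of LN cells, precursor B cells 2.13 and 0.0201%, erythroid cells 2.85 and 0.0959%, and immature neutrophils with Camp, Ngp and Ltf 6.38 and 0.0218%. Mouse F21 weighed most, with 94 of the precursor B cells (3.85% of its mELT cells, against 0.894 and 1.66% in E21 and E72) and 300 of the immature neutrophils (12.3% against 2.84 and 4.03%), and 13 of the LN erythroid cells came from E72. Blood left in the tissue is argued against by at least 30 progenitor or precursor B cells in each mELT library, cell types that hardly circulate. Bone marrow carried over when the cord was dissected stays open, since all 4 kinds were present in all 3 mELT libraries, and it cannot be told apart from cells formed in the tissue, which would give the same. Mouse F21 also held 34 of the 53 mELT plasma cells and the highest mELT shares of IGHA (21.3%) and of class-switched heavy chains (35.5%). Whether these cells have the same origin as the marrow-type cells was not tested.

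Other divisions of the 6 libraries into groups of 3 were compared, where 10 splits cannot give a share below 0.05. Every other division mixes both tissues in each group, so a tissue difference adds to the spread within groups and lowers the gene counts. Gene counts of 0 there follow from this design and do not measure chance. In B cells the division by tissue gave 20 genes with edgeR and the others 0 (so 1 split, the real one, reached 20), with 175 to 935 genes at an unadjusted p under 0.05. In T cells it gave 1571 and the others 0 (1 split), with 73 to 523 genes at an unadjusted p under 0.05. For lists it gave 5 in B cells, where the others gave up to 9 (6 splits), and 17 in T cells, where the others gave up to 15 (1 split).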
